A study of Homo sapiens with 26 samples.

How the data were processed

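Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 2 human breast cancer cell lines, T47D and MCF7, both of the luminal, oestrogen receptor-positive type. In T47D, 24 libraries were precipitated with an antibody against the HA epitope tag from cells that carried a control plasmid without GATA3 (empty vector) or a plasmid for HA-tagged GATA3: wild type, or 1 of 2 truncated forms, TR1 and TR2. GATA3 is a zinc finger transcription factor that is frequently mutated in breast cancer. Each of the 4 constructs was sampled in 3 arms: without siRNA, with a non-targeting siRNA (siNT), and with an siRNA against FOXA1 (siFOXA1), a forkhead factor that opens chromatin at many GATA3 sites. Each of the 12 anti-HA groups had 2 replicates. A further library each from T47D and MCF7 was precipitated with an antibody against GATA3 itself and had no replicate. The position of the truncations is not given in the labels, and neither is the source of the replicates (separate cultures or one). P-values that compare libraries therefore measure the spread between these libraries, which may be technical. The labels give no read-out of how far the siRNA lowered FOXA1.

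Per the submitters' processing notes, reads were aligned with BWA to hg19 and peaks were called with MACS 1.4. The deposited lists hold a position, a peak name and a score for each peak, with 1 list per library, so peaks were called per sample and not on pooled replicates. The score that the authors deposited has the range of the MACS 1.4 score (a transformed p-value), but no header states its scale. It was used here to rank peaks within a list and, in some of the alternatives below, to filter all anti-HA lists at 1 common cut. The lists were filtered and intersected before deposit, per the names of the deposited lists; with what they were intersected, and which control library was used, is not given in the sources used here. The numbers of reads are unknown, so a longer list can come from deeper sequencing or from more binding, and no interval for depth can be given. The lowest deposited score was about 70 in most lists and about 50 in the replicate 1 lists of both siRNA arms, for all 4 constructs. This difference in the authors' threshold is the same for all constructs and for both siRNAs within a replicate number, and values within replicate numbers are therefore given beside the pooled ones.

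The measures computed from the lists were the number of peaks per library (on the log2 scale), the share of a library's peaks that overlapped a peak of the T47D or MCF7 anti-GATA3 list by at least 1 bp, and the presence or absence of a peak in each merged region. Regions were the union of the peaks of the 24 anti-HA libraries that shared at least 1 bp, which gave 17820 regions. Coordinates are hg19 and 1-based. Regions with a peak in more than 1 of the 6 empty vector libraries were left out of the region tests, and a region was tested where at least 5 of the 12 libraries compared had a peak. Chance overlap was estimated from 100 random placements of the anti-GATA3 peaks on the same chromosomes.

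Peak numbers and shares were compared with exact two-sided permutation tests in which construct labels were permuted within the siRNA arm, or siRNA labels within the construct. With 2 against 2 libraries in each of 3 strata there are 216 arrangements, and the smallest p they can give is 0.00926. Regions were compared with Fisher's exact test, two-sided, on the numbers of libraries with a peak (6 against 6). P-values were adjusted by the Benjamini-Hochberg method within each measure, with a threshold of 0.05. Shares of regions are given with exact (Clopper-Pearson) 95% intervals, and shares of a list's peaks with Wilson 95% intervals. Both cover counting error alone, and regions are not independent replicates. The same holds for Fisher's exact tests between sets of regions, whose p-values count regions and do not measure the spread between libraries. The difference between constructs in the siFOXA1 effect was tested by permuting constructs within each siRNA. This gives 36 arrangements and a smallest p of 0.0556, so the test cannot reach the threshold.

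The regions named in the text followed a rule set before the data were examined: regions past the threshold were ranked by the difference in the number of libraries, then p, then the number of other HA-GATA3 libraries with a peak, then position, and the first 10 in each direction were listed. The text names all of them for wild type against TR1 and the first of each list, in rank order, for the other comparisons. Where none passed, the 10 with the largest differences were taken and are said not to have passed. No hg19 annotation or sequence was used here, so regions are named by position, and the planned comparisons of motifs, promoters and gene lists were not run.

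The alternatives tried were a stricter score threshold (above the median score of all anti-HA peaks), a coverage of at least 50% of the peak in place of 1 bp, merging of peaks closer than 500 bp, removal of empty vector peaks, another region filter, a stratified region test, lists of equal length, the MCF7 list in place of the T47D list, the replicate number as a block, and each replicate number left out. A uniform score floor of 70, equal list length for the shares, and leaving out single libraries were added after the data had been seen. The overlap functions and tests were tested on simulated data. For wild type against TR1, calls were drawn for 14900 regions with 200 changed, and the region test recovered 79 of 100 regions with a peak probability of 98% against 2% and 14 of 100 with 85% against 15%. It called none of the unchanged regions. The shares recovered were 73 and 10 of 100 for wild type against TR2, and 82 and 14 of 100 for TR1 against TR2. For siFOXA1 against siNT none was recovered, since the adjusted p of regions present in 6 of 6 and 0 of 6 libraries was 0.0513 there. All these shares depend on the 200 changed regions, since the adjusted p falls as more regions separate fully. In the real lists, fully separated regions did not pass for wild type against TR2 (adjusted p = 0.0592, Fisher's exact test). Nor did any for TR1 against TR2. No stronger pattern exists, so the simulated shares do not tell how many real differences these comparisons could find. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.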

Results

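The data comprised 26 peak lists. In T47D cells, 24 lists came from anti-HA precipitations of cells with the empty vector, wild-type GATA3, TR1 or TR2, each without siRNA, with siNT and with siFOXA1 (n = 2 in each group). The 2 remaining lists described endogenous GATA3 and held 15810 peaks in T47D and 27346 peaks in MCF7. The anti-HA lists of the 18 GATA3 libraries held between 232 and 7478 peaks, and those of the 6 empty vector libraries between 33 and 502. Replicates of a group shared a variable part of their lists. Of the 867 peaks of wild-type replicate 1 without siRNA, 82.8% lay at a replicate 2 peak. The corresponding share of the shorter list was 58.5% for TR1 and 36.6% for TR2 without siRNA, and 10.9% for the empty vector. With siNT it was 83.5% for wild type, 83.8% for TR1 and 77.2% for TR2. With siFOXA1 it was 86.1%, 64.7% and 87.6% in the same order.

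The first comparison asked how far the anti-HA signal stood above the background of the antibody in cells without tagged GATA3. HA-GATA3 libraries had 13.3-fold more peaks than empty vector libraries, a log2 difference of 3.74 (exact permutation test within siRNA arms, two-sided, p = 4.56e-05, the smallest it can give, adjusted p = 0.000228). The geometric mean was 143 peaks for the empty vector (n = 6), 3017 for wild type (n = 6), 2010 for TR1 (n = 6) and 1151 for TR2 (n = 6). The TR2 libraries without siRNA, with 232 and 313 peaks, lay below the longest empty vector list. In these lists 54.2% ± 9.31 (SD, n = 2) of the peaks overlapped an empty vector peak, compared with 12.2% ± 7.77 (SD, n = 2) for wild type and 16.2% ± 3.13 (SD, n = 2) for TR1 without siRNA. Within replicate numbers the log2 difference was 4.56 for replicate 1 and 2.91 for replicate 2.

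**Figure D1:**
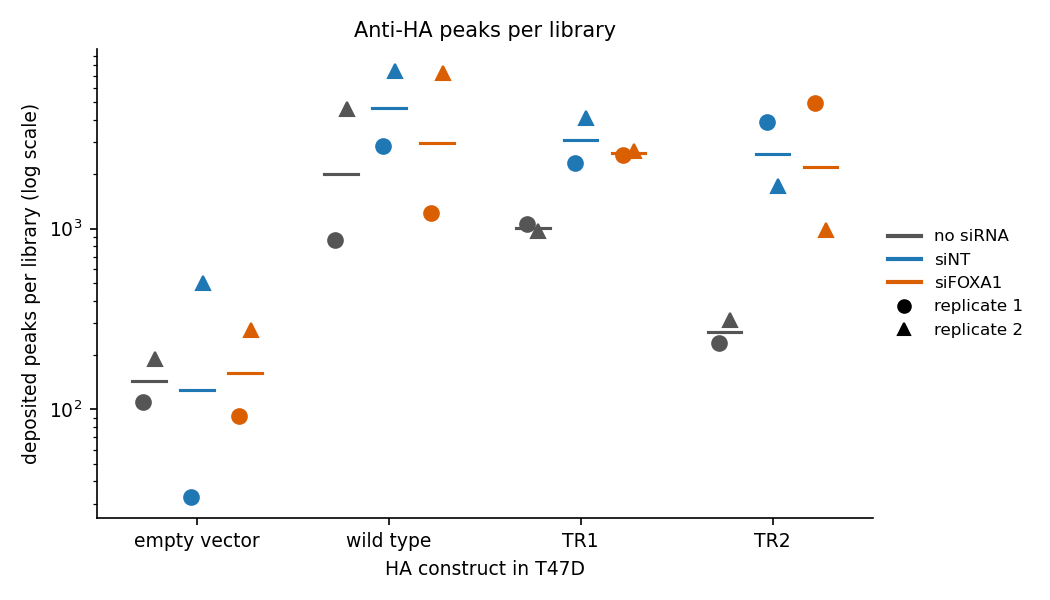
Number of deposited anti-HA peaks per library (log axis) by construct, with the siRNA arm in colour and the replicate number as the symbol; lines are geometric means of the 2 replicates. Empty vector lists held 33 to 502 peaks, and the wild-type lists 867 to 7478.

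The number of peaks did not separate the GATA3 constructs. The TR1 number was 0.666 times that of wild type (log2 difference -0.59, exact permutation p = 0.343, adjusted p = 0.428). The TR2 number was 0.382 times that of wild type (log2 difference -1.39, exact permutation p = 0.111, adjusted p = 0.231) and 0.573 times that of TR1 (log2 difference -0.80, exact permutation p = 0.139, adjusted p = 0.231). The sign of the first 2 differences was not the same in both replicate numbers. For TR1 against wild type the log2 difference was 0.35 in replicate 1 and -1.52 in replicate 2, and for TR2 against wild type it was 0.18 and -2.96. For TR2 against TR1 it was -0.16 and -1.44.

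The share of called peaks at endogenous T47D GATA3 sites was lower for both truncated forms than for wild type. Wild-type peaks lay at a T47D GATA3 peak in 80.5% ± 5.88 (SD, n = 6 libraries), TR1 peaks in 61.9% ± 11.7 (SD, n = 6) and TR2 peaks in 54.2% ± 16.5 (SD, n = 6). The share was 23.01% ± 9.65 (SD, n = 6) for empty vector peaks and at most 2.16% in any random placement for the 18 GATA3 lists. The difference from wild type was -18.7 percentage points for TR1 (exact permutation p = 0.00926, the smallest the design allows, adjusted p = 0.0185) and -26.3 percentage points for TR2 (exact permutation p = 0.00926, adjusted p = 0.0185). TR2 differed from TR1 by -7.62 percentage points, less than the spread between libraries (exact permutation p = 0.352). Within replicate 1 the difference from wild type was -23.2 points for TR1 and -41.4 points for TR2, and within replicate 2 it was -14.1 and -11.2 points. For TR2 against TR1 the values were -18.2 and 2.92 points. Replicate 1 of TR2 with siNT and with siFOXA1 held 93.1% and 95.2% of the 189 peaks of empty vector replicate 2 without siRNA, compared with 6.35% to 78.8% for the other GATA3 libraries, the highest of which was wild-type replicate 2 without siRNA. Without both libraries, a setting chosen after seeing the data, the TR2 difference from wild type was -16.3 points (exact permutation p = 0.037, adjusted p = 0.0494) and that from TR1 was 2.33 points. At MCF7 GATA3 peaks the share was 60.1% ± 6.54 (SD, n = 6) for wild type, 59.8% ± 6.84 (SD, n = 6) for TR1 and 49.4% ± 16.4 (SD, n = 6) for TR2. The difference from wild type at the MCF7 sites was -0.341 points for TR1 (exact permutation p = 0.963) and -10.7 points for TR2 (exact permutation p = 0.176), and TR2 differed from TR1 by -10.4 points (exact permutation p = 0.167). With a required coverage of 50% of the peak the differences at T47D sites were -19.6 and -24.95 points, and neither passed the threshold (adjusted p = 0.0556 for both, exact permutation test). With the 232 strongest peaks of each list they were -11.1 points for TR1 (adjusted p = 0.0741, exact permutation test) and -23.99 points for TR2 (adjusted p = 0.037). Without any 1 of the 4 wild-type siRNA libraries the TR2 difference lay between -25.2 and -27.3 points with an adjusted p of 0.0556 to 0.0741 (exact permutation test).

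**Figure D2:**
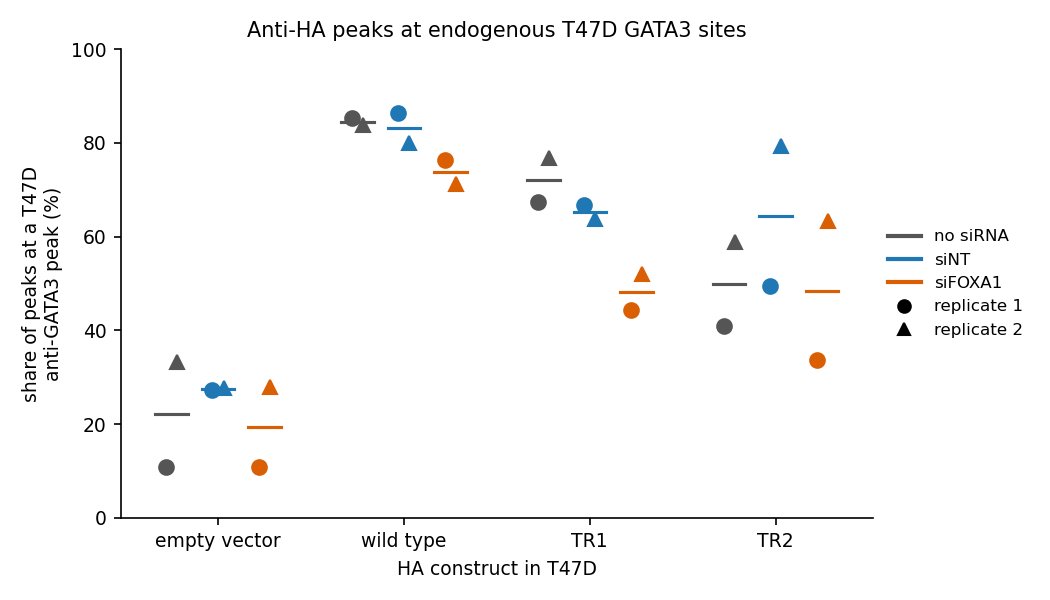
Share of each library's anti-HA peaks that overlapped a T47D anti-GATA3 peak (percent) by construct, with the siRNA arm in colour and the replicate number as the symbol; lines are means of the 2 replicates. Within each arm both wild-type libraries lay above both TR1 libraries and both TR2 libraries.

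The tagged proteins reached the stronger T47D GATA3 sites more often than the weaker ones. Of the 15810 T47D peaks, 50.8% had a peak in at least 1 wild-type library, 20.8% in at least 1 TR1 library, 17.98% in at least 1 TR2 library and 1.01% in at least 1 empty vector library. With the list divided by endogenous score into 4 equal parts, these shares were 85.5% for wild type, 45.3% for TR1 and 39.9% for TR2 in the highest part, and 24.7%, 7.87% and 7.11% in the lowest. The part of the length of the anti-HA lists in these shares was not tested. Of the T47D sites reached, 55.2% for wild type, 70.2% for TR1 and 72.2% for TR2 were shared with MCF7, against 41.5% of all T47D sites. The part of site strength and of list length in these differences was not tested.

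Single regions were then compared between wild type and TR1. Of 2002 regions tested, 38 carried a peak in 6 of 6 TR1 libraries and 0 of 6 wild-type libraries, and 73 in 6 of 6 wild-type and 0 of 6 TR1 libraries. These 111 regions passed the threshold (Fisher's exact test, p = 0.00216, adjusted p = 0.039). A further 67 regions carried a peak in all libraries of both constructs. The 2 sets differed in their relation to endogenous GATA3. All 73 wild-type regions lay at a T47D GATA3 peak (exact 95% interval 95.1% to 100%), while 16 of the 38 TR1 regions did (42.1%, 26.3% to 59.2%), against 94.3% of the other 1964 regions tested (Fisher's exact test for the TR1 regions, adjusted p = 5.5e-17). At MCF7 GATA3 peaks lay 60.3% of the wild-type regions (48.1% to 71.5%) and 42.1% of the TR1 regions. Of the TR1 regions, 15 (39.5%, 24.04% to 56.6%) lay at neither endogenous list, compared with 1.93% of the other regions tested (Fisher's exact test, adjusted p = 6.03e-15). The TR1 regions had no wild-type GATA3 peak in T47D by definition, while the other regions could enter the test through wild-type peaks. Part of these differences can therefore come from how the sets were picked.

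All passing TR1 regions tied in difference and p, so the rule ranked them by the number of TR2 libraries with a peak. The named TR1 regions are therefore those with the most TR2 calls. Among them, 6 carried a peak in 6 of 6 TR2 libraries. They were chromosome 1, 25363618 to 25364372; chromosome 2, 53194261 to 53194870 and 224809754 to 224810343; chromosome 3, 124492892 to 124493685; chromosome 5, 179891470 to 179892258; and chromosome 22, 43510789 to 43511461. The region at chromosome 2, 224809754 had no endogenous GATA3 peak in either cell line, and the regions on chromosomes 5 and 22 had one in both. The other 4 named TR1 regions carried a peak in 5 of 6 TR2 libraries and had no endogenous GATA3 peak in T47D or MCF7. They were chromosome 3, 50336879 to 50337486 and 186284270 to 186285481; chromosome 7, 940585 to 941392; and chromosome 10, 5664860 to 5665600. No empty vector library had a peak at any of these 10 regions. The named wild-type regions were ranked by TR2 calls in the same way. The first was chromosome 10, 82724046 to 82726926, which was 2881 bp wide and had an endogenous peak in both T47D and MCF7. It had a peak in 4 of 6 TR2 libraries. Chromosome 1, 151712221 to 151713120, chromosome 12, 109423470 to 109424202 and chromosome 3, 197230273 to 197231261 had an endogenous peak in T47D and none in MCF7. The other 6 were chromosome 2, 9970269 to 9971090 and 173818669 to 173819342; chromosome 11, 62275405 to 62276441 and 67079855 to 67080751; chromosome 14, 77554293 to 77555142; and chromosome 1, 108186137 to 108186948. All 6 had an endogenous peak in both cell lines. The regions at chromosome 2, 9970269 and chromosome 14, 77554293 had a peak in 1 of the 6 empty vector libraries.

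**Figure D3:**
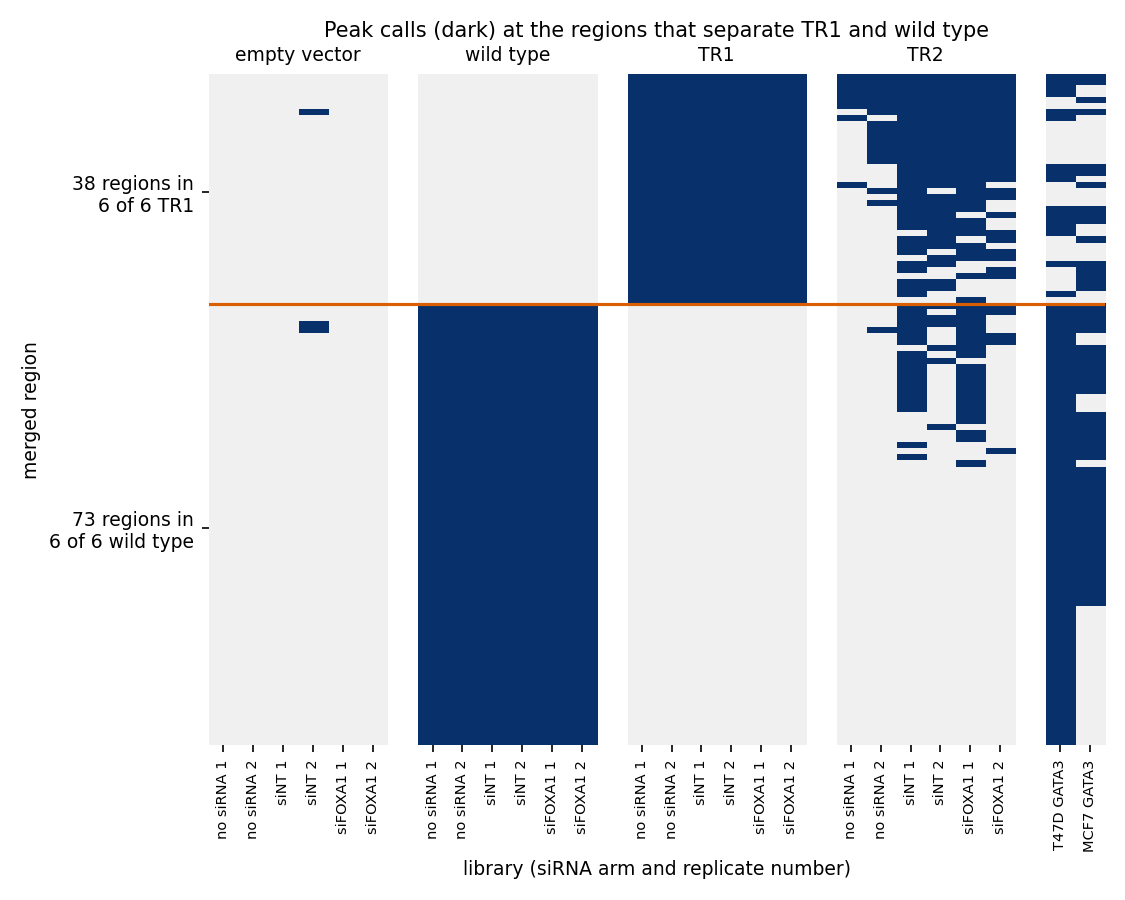
Peak calls (dark) in the 24 anti-HA libraries, by construct, arm and replicate, at the 38 regions called in 6 of 6 TR1 and 0 of 6 wild-type libraries (top) and the 73 regions called in 6 of 6 wild-type and 0 of 6 TR1 libraries (bottom), with overlap of the T47D and MCF7 anti-GATA3 lists at the right. The wild-type and TR1 blocks are uniform because the regions were selected on them; the TR2 libraries, which were not used to select the regions, had more calls in the upper block.

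The TR2 libraries, which took no part in that test, had peaks at the TR1 regions more often than at the wild-type regions. All 38 TR1 regions had a peak in at least 1 TR2 library and 31 of them (81.6%) in at least 3, whereas 27 of the 73 wild-type regions (37.0%) had a peak in at least 1 and 7 (9.59%) in at least 3 (Fisher's exact test for at least 1 library, p = 3.07e-12). The share with a peak was higher at the TR1 regions in 6 of 6 TR2 libraries. It was 21.1% against 0% in TR2 replicate 1 and 42.1% against 1.37% in TR2 replicate 2 without siRNA, and 89.5% against 26.0% and 84.2% against 8.22% with siNT. The number of regions past the threshold in wild type against TR1 depended on the test and the threshold. It was 46 with the stricter score threshold, 0 of 4765 regions with a filter of 3 of 12 calls, and 0 with a test stratified by arm, whose smallest p of 0.00926 cannot pass the adjustment over 2002 regions. With lists of equal length it was 219, of which 93 were TR1 and 126 wild-type regions. Without wild-type replicate 1 of the arm without siRNA it was 236, and without wild-type replicate 1 with siFOXA1 it was 192.

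In the comparison of wild type with TR2, none of 1696 regions passed the threshold, although 313 had an unadjusted p under 0.05 in Fisher's exact test, 23 of them with more calls in TR2 and 290 with more in wild type. The 8 regions in 6 of 6 TR2 and 0 of 6 wild-type libraries and the 54 regions of the opposite kind reached an adjusted p of 0.0592 (Fisher's exact test). The 8 TR2 regions included the 6 above that were shared with TR1, along with chromosome 2, 120980727 to 120981479 and chromosome 7, 87539446 to 87539891, which carried a peak in 5 of 6 TR1 libraries. Both comparisons used the same wild-type libraries, so part of this overlap can come from them. Regions with 6 wild-type and 0 TR2 calls were ranked by their number of TR1 calls. First came chromosome 12, 1230343 to 1232375 and chromosome 11, 133352805 to 133354348, which carried a peak in 4 and 3 of the 6 TR1 libraries. With the 232 strongest peaks of each list 49 of 136 regions passed, of which 16 were TR2 and 33 wild-type regions. Leaving out any 1 of the 6 wild-type libraries, of both TR2 siNT libraries or TR2 siFOXA1 replicate 1 let between 62 and 175 regions pass, most of them wild-type regions. Regions with at least 4 more TR2 than wild-type libraries lay at a T47D GATA3 peak in 16 of 30 cases (53.3%, exact 95% interval 34.3% to 71.7%), and those with at least 4 more wild-type libraries in 422 of 427 cases (98.8%, 97.3% to 99.6%). Both sets were picked on wild-type calls in T47D, so part of this difference can come from the selection.

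TR1 and TR2 could not be separated by region. None of 1377 regions passed, and 10 had an unadjusted p under 0.05 (Fisher's exact test), all with more calls in TR1. The region with the largest difference, chromosome 6, 38207511 to 38208624, was called in 6 of 6 TR1 and 0 of 6 TR2 libraries (p = 0.00216, adjusted p = 1, Fisher's exact test). Chromosome 5, 76468246 to 76469526 and chromosome 6, 140200957 to 140201704 were called in 5 TR1 libraries and in no TR2 library, and they did not pass either. In 24 regions all libraries of both constructs had a peak.

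Differences seen without siRNA were read out again in the siNT libraries, which are a separate set. Of 428 regions with a peak in both wild-type and neither TR1 library without siRNA, 182 (42.5%, exact 95% interval 37.8% to 47.4%) had the same pattern with siNT, and none had the opposite one. A TR1 peak with siNT was present at 181 of the 428. Of 174 regions with the TR1 pattern, 88 (50.6%, 42.9% to 58.2%) showed it again and none the opposite (Fisher's exact test over both sets, adjusted p = 5.53e-73). A wild-type peak with siNT was present at 55 of the 174. For wild type and TR2, 188 of 594 wild-type regions (31.6%) and 9 of 17 TR2 regions (52.9%) were found again, and 1 had the opposite pattern (Fisher's exact test, adjusted p = 1.4e-14). With siNT, 333 of the 594 had a TR2 peak and 6 of the 17 a wild-type peak. For TR1 and TR2, 13 of 344 TR1 regions (3.78%) kept the pattern, and 314 of the 344 had a TR2 peak with siNT. In the reverse direction, picked with siNT and read without siRNA, the shares found again were lower, 14.4% for wild type and 13.2% for TR1 in the first pair, and 14.3% for wild type and 3.11% for TR2 in the second.

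The siRNA arms addressed whether binding depended on FOXA1. The number of peaks with siFOXA1 was 0.777 times that with siNT over the 3 GATA3 constructs, a log2 difference of -0.36 that was within the spread between libraries (exact permutation test within constructs, two-sided, p = 0.528). It was -0.24 within replicate 1 and -0.49 within replicate 2, and without wild-type siFOXA1 replicate 1 it was 0.0656. The share of peaks at T47D GATA3 sites was 71.0% ± 13.6 (SD, n = 6) with siNT and 56.8% ± 16.4 (SD, n = 6) with siFOXA1. The difference of -14.1 percentage points did not pass the threshold (exact permutation p = 0.0556, adjusted p = 0.0741). It was -16.1 points within replicate 1 and -12.2 points within replicate 2. It passed without TR2 siNT replicate 1 or TR2 siFOXA1 replicate 2 (-19.1 points each, adjusted p = 0.037, exact permutation test), and with the 232 strongest peaks of each list (-12.9 points, adjusted p = 0.037). Without TR2 siNT replicate 2 it was -9.13 points and without TR2 siFOXA1 replicate 1 it was -9.17 points. By construct the difference was -9.47 points for wild type, -17.0 points for TR1 and -15.9 points for TR2. In the empty vector lists the share was 27.5% ± 0.295 (SD, n = 2) with siNT and 19.4% ± 12.1 (SD, n = 2) with siFOXA1. The siFOXA1 effect on peak number differed between TR1 and wild type by 0.40, between TR2 and wild type by 0.41 and between TR2 and TR1 by 0.00368 on the log2 scale (exact permutation p = 0.833, 0.833 and 1). In the same order it was 1.38, 1.58 and 0.19 in replicate 1 and -0.58, -0.77 and -0.19 in replicate 2. With 36 arrangements that test cannot give a p under 0.0556.

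No single region passed the test of siFOXA1 against siNT. Of 2099 regions, 244 had an unadjusted p under 0.05 in Fisher's exact test, 191 with more siNT and 53 with more siFOXA1 calls, and the smallest adjusted p was 0.13. The following counts are therefore descriptions. In 27 regions all 6 siNT libraries and no siFOXA1 library had a peak, among them chromosome 2, 217615269 to 217616263; chromosome 5, 35476614 to 35477848; and chromosome 13, 82448150 to 82448867. All 3 had an endogenous GATA3 peak in T47D and MCF7. The opposite pattern, 6 of 6 siFOXA1 and 0 of 6 siNT libraries, occurred in 5 regions: chromosome 7, 69124483 to 69125387; chromosome 10, 121378062 to 121378741; chromosome 12, 87838225 to 87838916; and chromosome 20, 38946063 to 38946833 and 47302628 to 47303337. The first 2 had an endogenous peak in T47D alone and the other 3 in MCF7 alone. With each library held to the 982 strongest peaks, 34 regions passed, 12 of them with more siFOXA1 calls and 22 with more siNT calls. Without wild-type siNT replicate 1 there were 102, and without wild-type siFOXA1 replicate 2 there were 106.

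Within each construct, regions present in both siNT libraries were followed into the siFOXA1 libraries. Of 2244 wild-type regions, 648 (28.9%, Wilson 95% interval 27.0% to 30.8%) were kept in both siFOXA1 libraries and 312 (13.9%) were found in neither. TR1 kept 679 of 1779 regions (38.2%, 35.9% to 40.4%) and lost 782 (44.0%). TR2 kept 345 of 1180 (29.2%, 26.7% to 31.9%) and lost 531 (45.0%). The wild-type siFOXA1 lists held 1219 and 7291 peaks. The kept shares changed with the siNT replicate they were taken from, beyond these intervals, as given below. The part of list length in these shares and the differences between constructs were not tested. Regions present in both siFOXA1 libraries and in neither siNT library numbered 120 of 987 for wild type (12.2%, Wilson 95% interval 10.3% to 14.3%), 568 of 1538 for TR1 (36.9%, 34.6% to 39.4%) and 224 of 742 for TR2 (30.2%, 27.0% to 33.6%). The gained regions lay at T47D GATA3 peaks less often than the regions lost or kept. Gained regions had no siNT peak by definition, while those lost or kept had one in both siNT libraries. The T47D anti-GATA3 list carries no siRNA label. Part of this difference can therefore come from how the classes were picked. Of the TR1 regions, 30.1% of those gained (exact 95% interval 26.4% to 34.1%), 73.8% of those lost (70.6% to 76.8%) and 78.6% of those kept (75.4% to 81.7%) were endogenous T47D sites (Fisher's exact test of gained against the others, adjusted p = 2.78e-80). For wild type the shares were 41.7%, 90.7% and 98.5%, and for TR2 45.1%, 88.3% and 89.6% (adjusted p = 6.4e-48 and 1.87e-40 for the gained regions, Fisher's exact test). Of the gained TR1 regions, 46.5% lay at no endogenous GATA3 peak of either cell line, compared with 31.7% for wild type and 34.4% for TR2.

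**Figure D4:**
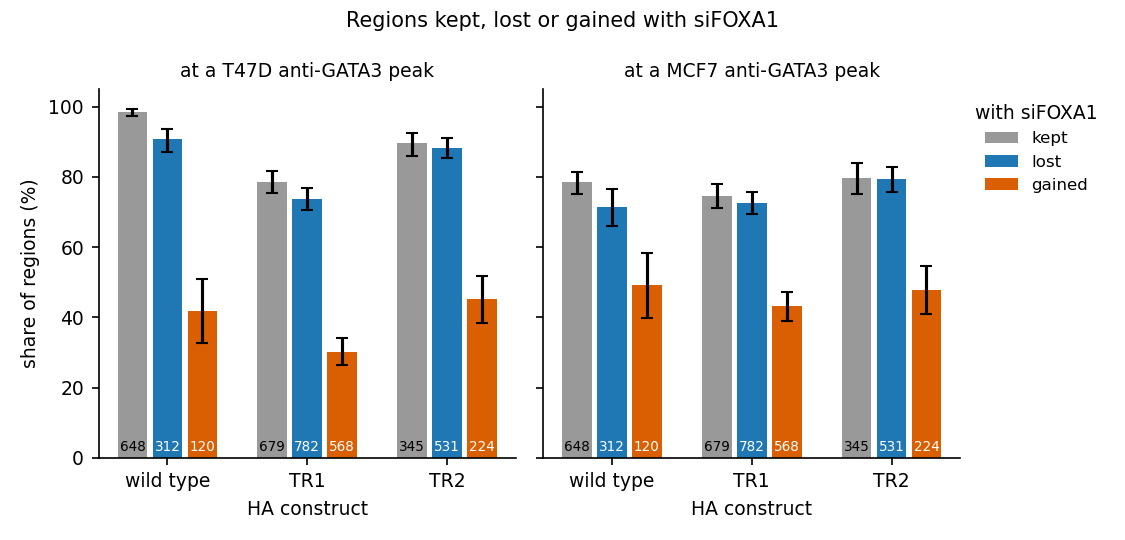
Share of regions (percent) at a T47D (left) or MCF7 (right) anti-GATA3 peak, for regions of each construct kept, lost or gained with siFOXA1; bars carry exact 95% binomial intervals and the number of regions at their base. The gained regions, which by definition had no siNT peak, had the lowest share in each construct, 30.1% to 45.1% for T47D and 43.1% to 49.2% for MCF7.

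Endogenous GATA3 was profiled in 1 library per cell line, so differences between the lines have no replicate check. Of the T47D peaks, 6567 of 15810 (41.5%, Wilson 95% interval 40.8% to 42.3%) lay at an MCF7 peak, against 1.01% after random placement. Of the MCF7 peaks, 6425 of 27346 (23.5%, 22.997% to 24.001%) lay at a T47D peak, against 0.599% after random placement. The median peak width was 300.0 bp in T47D and 750.0 bp in MCF7, and with a required coverage of 50% of the peak the shared part of the MCF7 list was 6.66%.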

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

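The uniform score floor of 70, equal list length for the shares and the removal of single libraries were chosen after seeing the data. Of the values under settings chosen before the data were examined 107 kept their direction and side of the threshold (counts and shares: their size), as did 173 under later ones. In 7 and 3 the sign turned; none of these was or became a call. The cause of the changes below was not tested unless stated.

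The share of peaks at T47D GATA3 sites, TR1 and TR2 against wild type, no longer passed with 50% of the peak covered (-19.6 and -24.95 points) or with the MCF7 list (-0.341 and -10.7 points). The MCF7 list comes from another cell line and 41.5% of the T47D sites lay in it, so its values concern a partly different set of sites. With equal list length TR1 did not pass (-11.1 points), whereas siFOXA1 against siNT did (-12.9 points), as it did without both TR2 replicate 1 siRNA libraries (-14.2 points; TR2 against wild type -16.3, TR2 against TR1 2.33). With 1 replicate number or 1 library left out, the TR1 difference lay between -14.1 and -23.2 points, the TR2 difference between -11.2 and -41.4, the siFOXA1 difference between -9.13 and -19.1, and TR2 against TR1, with a turn of sign, between -18.2 and 2.92. The log2 excess over the empty vector lay between 2.91 and 4.56, and its call was kept without any single library. The log2 peak number turned sign for TR1 against wild type (-1.52 to 0.35), TR2 against wild type (-2.96 to 0.18) and siFOXA1 against siNT (-0.795 to 0.0656), and the difference in its siFOXA1 effect for TR1 minus wild type (-0.58 to 1.38), TR2 minus wild type (-0.77 to 1.58) and TR2 minus TR1 (-0.19 to 0.19; -0.0105 without empty vector peaks). With 1 replicate number per group the smallest possible exact permutation p is 0.25 for pairs of groups, and the smallest adjusted p for the empty vector 0.0781, so the loss of a call there (the empty vector's included) says nothing of stability.

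The count of regions for wild type against TR1 (111) was 0 with a filter of 3 of 12 calls (4765 tested), 46 with stricter peaks, 0 in the stratified test and 219 with equal list length. Equal list length gave 49 regions for wild type against TR2 and 34 for siFOXA1 against siNT. Leaving out a replicate number or a library gave 0 to 236 regions for wild type against TR1, 0 to 175 for wild type against TR2 and 0 to 106 for siFOXA1 against siNT. The filter and the stratified test act through the number of regions tested and the smallest p.

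Of the regions found again with siNT, stricter peaks left 37.1% for TR1 against wild type, and the uniform floor 35.98% for wild type against TR1. Picked with siNT and read without siRNA, the shares were 14.4% (wild type, not TR1), 13.2% (TR1, not wild type), 14.3% (wild type, not TR2) and 3.11% (TR2, not wild type). The wild-type share kept with siFOXA1 was 24.1% with the uniform floor. From siNT replicate 1 or 2 alone it was 24.4% and 11.6% for wild type, 33.8% and 23.6% for TR1, and 13.9% and 24.01% for TR2. Of the T47D sites 40.2% (50% covered) and 38.1% (stricter peaks) lay in the MCF7 list, and of the MCF7 sites 6.66% and 21.4% lay in the T47D list.

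The labels do not pair the replicate numbers, and not all correlations of same-numbered deviations were above 0.1 (5 of 12 pairs of groups, range -0.0121 to 0.241), so the numbers were not used as pairs. In part they may still mark batches, as the score floor and the shared peaks of some replicate 1 lists show. With the replicate block the siFOXA1 difference in share, -14.1 points, passed (exact permutation, adjusted p = 0.0417), 0 regions passed for wild type against TR1 since its smallest p cannot pass, and the kept share averaged over replicate numbers was 41.3% for wild type and 40.004% for TR2. The block changed no other call. Without empty vector peaks the empty vector comparison has no value. The motif, promoter and gene-list comparisons and their alternatives were not run. The unknown sequencing depth limits all peak numbers.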

Other observations

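Of the tests in this part, those on regions gained with siFOXA1, on the empty vector replicate, on other groupings for TR2 and siFOXA1, with balanced groupings, with weak peaks removed by score, and with equal list lengths were chosen after the result was seen.

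Endogenous GATA3 sites were unevenly spread over the genome of the 2 cell lines. The 5 Mb window with the most T47D sites was chromosome 3, 170000001 to 175000000, with 103 T47D and 77 MCF7 peaks, followed by chromosome 3, 185000001 to 190000000, with 100 and 68. In MCF7 the window with the most sites was chromosome 10, 60000001 to 65000000, with 148 MCF7 and 56 T47D peaks, followed by chromosome 9, 80000001 to 85000000, with 144 and 18. Chromosome 10, 5000001 to 10000000 stood among the first 5 windows of both lines, with 82 T47D and 135 MCF7 peaks.

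TR1 and TR2 peaks lay at endogenous T47D GATA3 sites less often than wild-type peaks. Background called in the empty vector lists does not account for this on its own. Without peaks that overlapped an empty vector peak the differences were -18.9 points for TR1 and -20.7 points for TR2 (exact permutation test, adjusted p = 0.037 for both). The empty vector lists are short (33 to 502 peaks) and of unknown depth, so background called only in longer lists is not excluded. Without siRNA, with siNT and with siFOXA1 the TR2 difference was -44.3, -37.1 and -42.8 points in replicate 1. In replicate 2 it was -25.0, -0.703 and -7.84 points. Weak peaks do not account for the lower shares on their own either: among the peaks above the median score of 106.18 the differences were -18.5 and -27.4 points (adjusted p = 0.0185 for both, exact permutation test). That cut was the same for all lists, whose depths are unknown, so peaks that are weak for their own list are not excluded. The unequal length of the lists stays open for both forms. With the 232 strongest peaks of each list the TR1 difference was -11.1 points (adjusted p = 0.0741, exact permutation test). The TR2 difference was -23.99 points (adjusted p = 0.037, exact permutation test), against -26.3 points with the full lists. For TR2 most of the difference thus remained, but this does not settle the part of list length. The cut takes no peak from TR2 replicate 1 without siRNA, where 60.8% of the peaks overlapped an empty vector peak. It also does not equalise the unknown sequencing depth. A change in the sites that the truncated proteins bind stays a hypothesis, and the amounts of tagged protein in the cells were not measured here.

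Regions that gained a TR1 peak with siFOXA1 also gained one in the other constructs more often than they lost one. Of the 568 regions, 286 had more siFOXA1 than siNT calls in TR2 and 10 had fewer, and the numbers for wild type were 143 and 30. Longer lists with siFOXA1 do not account for the TR2 part: in replicate 2, where the siFOXA1 list was the shorter one (982 against 1715 peaks), the share of these regions with a peak rose from 1.94% to 18.8%, and in replicate 1, with 982 peaks in each list, it rose by 11.4 points. For wild type both siFOXA1 lists were the shorter ones. As deposited, the share rose from 21.8% to 42.4% in replicate 2. In replicate 1 it rose by 2.82 points (43 regions with a siFOXA1 peak alone and 27 with a siNT peak alone). With the 982 strongest peaks of each list the wild-type share rose by 9.51 points in replicate 1 and by 9.86 points in replicate 2. Longer lists are thus argued against for wild type too, although its replicate 1 rise as deposited was small. Background of the HA antibody is argued against. Of the 573 regions before the empty vector filter, 0.698% (4 regions) had a peak in an empty vector siFOXA1 library. However, those 2 lists are short (92 and 275 peaks) and their depth is unknown. It may be that lowered FOXA1 moves both truncated forms of GATA3 to a shared set of other sites. Wild type may share in this, but the part of list length is left open there and its replicate 1 rise as deposited was small. This is a hypothesis found and tested on the same libraries, and off-target effects of the siRNA were not tested.

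Empty vector replicate 1 without siRNA shared 79.1% of its 110 peaks with wild-type replicate 1, 79.1% with TR1 replicate 1 and 71.8% with TR2 replicate 1, but 12.7%, 11.8% and 10.9% with the replicate 2 libraries of the same constructs. The ratio was at least 6.21, as a background specific to the replicate 1 libraries of this arm would give. Among the 71 peaks found in all 4 replicate 1 lists, 14.1% lay at a T47D GATA3 peak (exact 95% interval 6.97% to 24.4%). Empty vector cells carried no tagged GATA3, so in their list these peaks cannot be binding of the tagged protein. The strongest of the 71 peaks by score was at chromosome 7, 61969006 to 61969455. Next, with equal scores, came chromosome 10, 42389267 to 42389566, chromosome 1, 121484899 to 121485448 and chromosome 15, 68132380 to 68132702.

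For wild type against TR1, 1 of 100 groupings of the 12 libraries, the real one, gave 111 regions past the threshold, and the highest of the others gave 0. This argues against chance in the choice of libraries for this count. The 0 comes in part from the adjusted threshold, as the other groupings held up to 36 regions in 6 and 0 libraries. For wild type against TR2, TR1 against TR2 and siFOXA1 against siNT the real grouping gave 0 regions, as did all 100 groupings in each case, which decides nothing, since no grouping can give fewer. A count of regions with calls in 6 libraries of one group and 0 of the other was added after the data had been seen. It was 111 for wild type against TR1 (at most 36 in the 99 other groupings), 62 for wild type against TR2 (at most 39), 32 for siFOXA1 against siNT (at most 20) and 1 for TR1 against TR2 (at most 13). Among groupings balanced over the siRNA arms, or over the constructs for the siRNA, the highest of 99 others gave 4, 9, 20 and 3 in the order wild type against TR1, wild type against TR2, siFOXA1 against siNT and TR1 against TR2. In the first 3 comparisons 1 of 100 groupings of either kind, the real one, gave as many, which argues against chance in the choice of libraries. It does not exclude chance, since 100 groupings cannot show less than 1 in 100 and the count was chosen afterwards. No single region passed the threshold in wild type against TR2 or siFOXA1 against siNT. For TR1 against TR2, 12 of the 100 free groupings gave as many, and chance cannot be excluded.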
